A study of Mus musculus with 3 samples.

How the data were processed

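Total RNA from frozen midbrain of C57BL/6 mice at postnatal day 3 was sequenced in 3 libraries, 1 wild-type (WT) and 2 labelled FGR, an abbreviation that the labels do not spell out and that is used here as given. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a TruSeq RNA kit. HISAT2 is named per the submitters' processing notes. Its version, the genome build and the counting tool are not given in the sources used here, so no coordinates are printed.

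The deposited table of each library lists 49585 genes with an Ensembl identifier, a symbol, a raw read count and a length. The authors also deposited an RPKM value per gene, which equalled the value computed from count, length and total to within 0.1 percent in every row and was not used further. Identifiers of 49326 genes were found in GENCODE M21 after the version suffix was dropped. Where a symbol belonged to more than 1 identifier (93 symbols), gene lists used the identifier with the highest total count.

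The deposited counts summed to 52874311 in WT, 58444481 in FGR replicate 1 and 46240262 in FGR replicate 2. The small cytoplasmic RNA genes Rn7s1 and Rn7s2 took 6.48% of the counts in WT and 7.19% and 7.87% in the FGR libraries. Their counts were nearly equal to each other in every library (1700819 and 1724680 in WT), so a read from such near-identical copies may have been counted at each copy or split between them, and values of close paralogs (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b) are uncertain. Whether counting used the strand is not given, so antisense transcripts (Dlx6os1, Cpeb1os1) cannot be told apart from overlapping genes.

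Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10), TMM scaling and the two-sided quasi-likelihood F test of FGR against WT over 25561 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, which came from the FGR pair, so the lone WT library was assumed to vary like the FGR libraries. The labels do not say that the FGR libraries came from separate animals or litters, so p-values measure only the spread between these samples. Levels of Xist and Y-linked genes differed between the FGR libraries as between the sexes, so this spread was not technical alone. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. CPM values are TMM-scaled and are given for FGR as mean ± SD over n = 2. For a gene at 0 in a group, the fold is a bound against a floor of 3 counts over that group. A group total of 1 to 3 counts is given as a ratio with an exact 95% binomial interval. Intervals and floors cover counting error only.

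Counts of genes by size used log2 CPM with a prior count of 2 for genes with a mean CPM of at least 1 and needed no test. For lists of genes, camera in limma 3.58.1 was run with a preset inter-gene correlation of 0.01 over the 54 of 55 lists that had at least 5 tested members. It was repeated with an estimated correlation, and fry was run beside it. That correlation and its test rested on the 1 residual degree of freedom, so hardly any list could pass. A call lost there cannot decide whether the list changed. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 called genes with the largest rise and the 10 with the largest fall (mean CPM of at least 1, both FGR libraries on the same side), the 5 smallest p-values in each direction, the 3 smallest p-values and the most abundant gene of each list that passed and of 10 fixed lists, the gene Fgr, and 5 sex-linked genes. Predicted genes and pseudogenes were passed over; 3 stood among the largest rises and 0 among the largest falls. The rule named 147 tested genes, of which 106 were called, and Fgr, which was not tested. Some of the genes it named are not reported here.

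The tests were tried on simulated counts for FGR against WT, with the means, library sizes and trended dispersions of the real libraries and known changes. Over 25026 simulated genes, edgeR called 47.8% of 67 genes changed 1.5-fold, 91.0% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 8 false calls. The changed genes were drawn from those at a mean CPM of at least 1, so these rates do not cover genes below that. A list of genes raised 1.5-fold was called by camera, and 0 of 50 unchanged lists were. Genes were drawn independently and WT varied like the FGR libraries. The simulation therefore could not show false list calls from genes that move together or from an unusual WT library. Alternatives covered scaling by DESeq2 size factors or library size, filters, DESeq2 1.42.0, limma-voom, a robust fit, another threshold, removal of abundant RNA genes and removal of each FGR library. A GC and length offset, protein-coding genes alone, and removal of X- and Y-linked genes were added after the data had been seen.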

Results

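Gene expression in the midbrain of C57BL/6 mice was profiled at postnatal day 3 by RNA sequencing of total RNA. The series held 1 WT library and 2 libraries labelled FGR, with total counts of 52874311 (WT), 58444481 (FGR replicate 1) and 46240262 (FGR replicate 2). The comparison the design implies is how the midbrain transcriptome of FGR mice differed from that of WT mice. With 1 WT library, no WT spread was measured, and any difference of that library in litter, dissection or preparation cannot be told apart from the group. The gene Fgr, which shares its symbol with the group name, had 6 counts in WT and 3 and 4 counts in the FGR libraries, too few to be tested.

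In FGR midbrain, transcription factors and peptides of the hypothalamus and ventral forebrain and genes of the meninges were lower than in WT. So were some genes of astrocytes, oligodendrocyte precursors and microglia. Regional genes of the midbrain, haemoglobins and the genes Slc6a2 and Dbh of noradrenaline transport and synthesis were higher. The calls that camera made for the lists of these groups at a preset correlation were lost with an estimated correlation (adjusted p = 0.641 for each). That test had 1 degree of freedom, so hardly any list could pass, and the loss does not decide. The preset correlation is itself an assumption that these libraries cannot check. By edgeR's quasi-likelihood test, 1087 of 25561 genes were called at an adjusted p under 0.05, 424 higher and 663 lower in FGR. Of the calls, 190 differed at least 2-fold, 49 of them higher and 141 lower. Both FGR libraries lay on the same side of WT for all 1087. The test all but requires this, because its spread came from the gap between them. The share of calls that were higher was 39.0%, against 24.4% when libraries were scaled by their totals alone and 47.7% with a GC and length offset. DESeq2 called 357 genes. In the same edgeR test with FGR replicate 1 set alone against the other libraries, 187 genes were called, and with FGR replicate 2 set alone 10 were. The common dispersion was 0.00832 with WT set alone, 0.0196 with FGR replicate 1 alone and 0.0219 with FGR replicate 2 alone. In the latter 2 fits the spread came from a pair of WT and FGR, so their counts are not comparable with 1087.

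**Figure D1:**
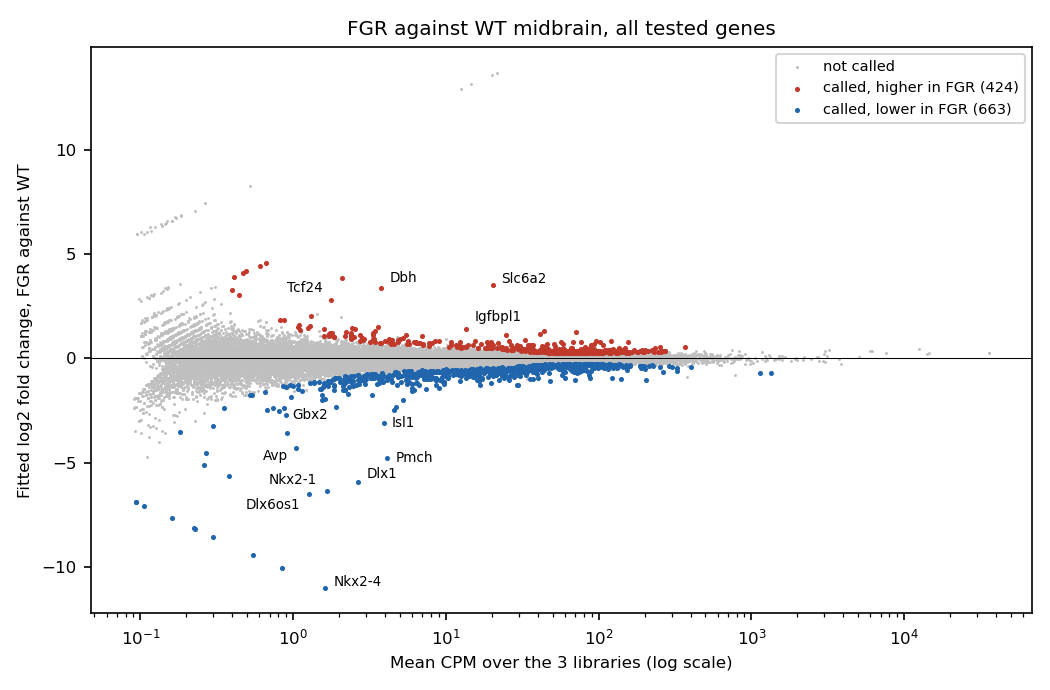
Fitted log2 fold change of FGR against WT (y axis) against mean CPM over the 3 libraries (x axis, log scale) for the 25561 tested genes, with 424 genes called higher in red, 663 called lower in blue and the others in grey. Labels mark genes among the largest changes. Fitted values of genes at 0 in a group depend on the prior count, and the grey points above 12 are Y-linked genes found in FGR replicate 2.

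Among called genes with a mean CPM of at least 1, the largest falls were mostly those of genes of the hypothalamus and ventral forebrain. Pmch, the precursor of melanin-concentrating hormone of the lateral hypothalamus (ENSMUSG00000035383.7), was at 11.5 CPM in WT and 0.423 ± 0.0109 CPM in FGR (SD, n = 2), a log2 fold change of -4.75 ± 0.20 (SE; edgeR adjusted p = 2.66e-08). Nkx2-1, a transcription factor that specifies ventral forebrain and hypothalamus (ENSMUSG00000001496.15), fell from 4.89 to 0.0564 ± 0.0178 CPM (adjusted p = 2.66e-07). The homeobox gene Dlx1 of forebrain GABA neurons fell 61.0-fold, and Dlx6os1, an antisense transcript of the Dlx locus, 90.7-fold. Nkx2-4 had 262 counts in WT and 0 in either FGR library, at least 168-fold lower. Avp, which encodes vasopressin, fell 19.5-fold, the LIM homeobox gene Isl1 8.57-fold, Sim1, needed for neuroendocrine hypothalamic neurons, 5.48-fold, the Wnt receptor gene Fzd5 4.99-fold and Gbx2 4.94-fold. Baiap3, a gene of vesicle exocytosis, fell from 105.8 to 51.6 ± 0.987 CPM.

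Of the 18 members of the diencephalon and hypothalamus list, 11 fell and 1 rose, or 13 and 1 adjusted over the list alone, and the median log2 fold change was -2.38 (camera adjusted p = 2.44e-33, and adjusted p = 0.641 with an estimated correlation). The member that rose was Lhx9, at 105.1 CPM in WT and 180.9 ± 12.8 CPM in FGR. In the striatum and ventral forebrain list, 7 of 14 members fell (9 adjusted over the list alone) and the median was -2.45 (camera adjusted p = 4.35e-27, and adjusted p = 0.641 with an estimated correlation). Rarb of this list was at 6.61 CPM in WT and 6.90 ± 0.111 CPM in FGR. Of 6 pituitary members, Cga and Tbx19 fell to 0 counts, at least 23.8-fold and 9.63-fold lower, also the 2 that fell adjusted over the list alone. The pituitary list was called lower (camera adjusted p = 9.90e-04, and adjusted p = 0.641 with an estimated correlation). This call was lost without a filter on low counts (adjusted p = 0.0788) and with camera on DESeq2's statistics (adjusted p = 0.0610).

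The cortex and hippocampus list was called higher, with 3 members higher, 1 lower (5 and 1 adjusted over the list alone) and a median of 0.12, though its mean was -0.14 because Fezf2 fell. The list's camera adjusted p was 0.0350, the adjusted p = 0.641 with an estimated correlation, and the call was lost without a filter on low counts (adjusted p = 0.0840). Fezf2 had 40 counts in WT and 3 in FGR, all in FGR replicate 2, a ratio of 0.0389 (95% interval 0.00770 to 0.122). Without FGR replicate 1 the ratio was 0.0883 (95% interval 0.0175 to 0.277), and without FGR replicate 2, at 0 counts, Fezf2 was at least 14.4-fold lower. The neuronal transcription factor genes Mef2c and Bcl11b rose 1.61-fold and 1.40-fold, the latter not called in a robust fit (adjusted p = 0.101), and Lmo3 was at 122.0 CPM in WT and 146.3 ± 8.31 CPM in FGR (adjusted p = 0.0670).

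Among the largest rises were those of Slc6a2, Dbh and Rln3. Slc6a2, the noradrenaline transporter gene (ENSMUSG00000055368.14), was at 2.55 CPM in WT and 29.2 ± 5.01 CPM in FGR, a log2 fold change of 3.52 ± 0.18 (adjusted p = 1.32e-07). Dbh, which encodes the enzyme that makes noradrenaline from dopamine, rose 10.3-fold. Rln3, a peptide gene of the pontine nucleus incertus, rose 4.11-fold. Tcf24, at 0.353 CPM in WT and 3.26 and 1.66 CPM in the FGR libraries, rose 7.01-fold, Stra6l 2.97-fold, Cpeb1os1 2.74-fold, Myh8, a skeletal muscle myosin, 2.72-fold and Skor1 2.66-fold. The calls of Cpeb1os1 and Skor1 were lost in limma-voom (adjusted p = 0.0545 and 0.0657), that of Skor1 also in a robust fit (adjusted p = 0.0925). Of the hindbrain and spinal Hox list only 4 genes were tested, too few for the list test. Hoxa2 and Hoxb3 were called higher, named here after their values were seen, and all 39 Hox genes summed to 17 counts in WT and 129 and 155 counts in the FGR libraries.

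Of 18 regional genes of the midbrain, 15 were higher in both FGR libraries, of which 10 rose, and 0 fell, or 11 and 0 adjusted over the list alone. The median log2 fold change was 0.39 (camera adjusted p = 2.14e-15; adjusted p = 0.641 with an estimated correlation). Tfap2d rose from 13.7 to 30.4 ± 2.64 CPM, En2, a gene of the midbrain-hindbrain boundary, from 20.9 to 38.7 ± 1.92 CPM and Meis2 from 67.8 to 118.7 ± 13.2 CPM. Tfap2b rose 1.30-fold, a call lost in DESeq2 (adjusted p = 0.694), in a robust fit (adjusted p = 0.186), under a stricter filter (adjusted p = 0.0824) and with protein-coding genes alone (adjusted p = 0.0577). Among the genes with the smallest p-values, the heparan sulphate enzyme gene Ndst4 rose 2.45-fold, Trappc10 1.81-fold and Ttc9c 1.74-fold.

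Of 19 dopamine neuron genes, 5 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00740, and adjusted p = 0.645 with an estimated correlation). The list's call was lost under a stricter filter (adjusted p = 0.0501). Slc6a3, the dopamine transporter gene (ENSMUSG00000021609.6), fell from 47.5 to 20.02 ± 3.18 CPM, a log2 fold change of -1.25 ± 0.12 (adjusted p = 4.21e-05). The transcription factor genes Foxa1 and Lmx1a, which specify midbrain dopamine neurons, fell 2.50-fold and 1.77-fold, the latter not called in DESeq2 (adjusted p = 0.0711). Th, the rate-limiting enzyme gene of dopamine synthesis, named after its values were seen, was at 14.1 CPM in WT and at 10.2 and 11.1 CPM in the FGR libraries (adjusted p = 0.122), and Sox6 was at 53.3 and 55.2 ± 1.24 CPM.

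**Figure D2:**
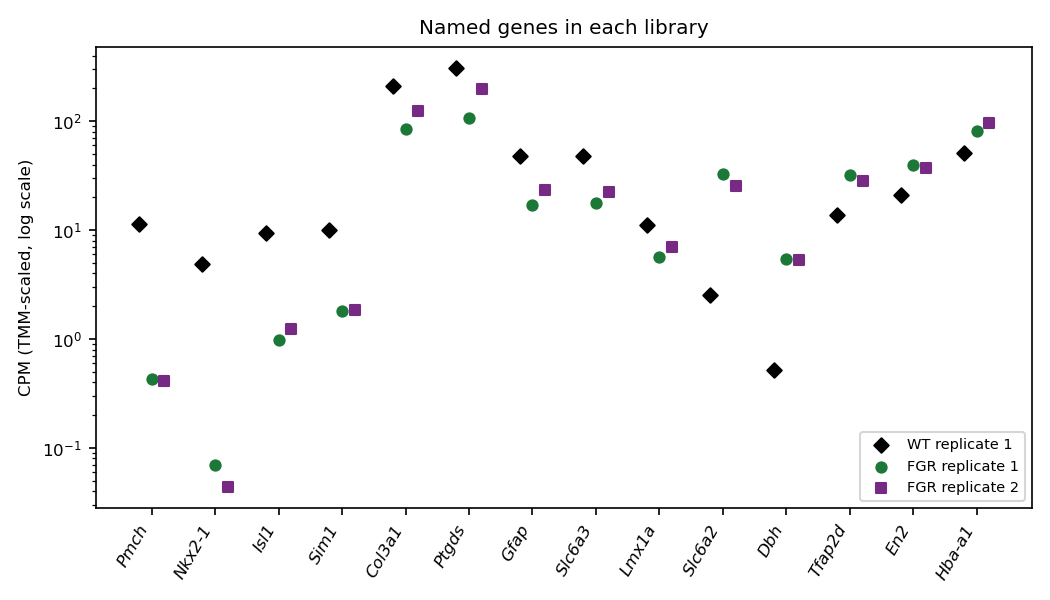
CPM (y axis, TMM-scaled, log scale) of 14 named genes in the WT library (black), FGR replicate 1 (green) and FGR replicate 2 (purple), 1 point per library. Pmch lay at 11.5 CPM in WT and near 0.423 CPM in FGR, and Slc6a2 at 2.55 CPM in WT and a mean of 29.2 CPM in FGR.

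Genes of the meninges and fibroblasts were lower in both FGR libraries for 18 of 18 members, of which 14 fell (17 adjusted over the list alone; camera adjusted p = 3.12e-24, and adjusted p = 0.641 with an estimated correlation). The median log2 fold change was -0.89, with -1.24 in FGR replicate 1 and -0.61 in FGR replicate 2. The collagen gene Col3a1 was at 210.4 CPM in WT and 104.8 ± 28.0 CPM in FGR, the growth factor gene Igf2 at 177.8 and 93.6 ± 27.3 CPM, Ptgds, which makes prostaglandin D in the leptomeninges, at 308.8 and 152.6 ± 63.5 CPM, and the fibronectin gene Fn1 at 49.2 and 31.4 ± 1.26 CPM. Calls of Col3a1, Igf2 and Ptgds were lost in DESeq2 (adjusted p = 0.359, 0.525 and 0.715) and in a robust fit (adjusted p = 0.559, 0.610 and 0.679).

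Of 14 mural cell genes 4 fell (5 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 4.14e-07, and adjusted p = 0.641 with an estimated correlation). Among them were Vtn, from 73.8 to 35.4 ± 3.40 CPM, Rgs5 (1.39-fold) and the channel subunit gene Abcc9 (1.58-fold). Of 18 endothelial genes 4 fell (6 adjusted over the list alone, where 1 rose), with a median of -0.28 (camera adjusted p = 0.00397, and adjusted p = 0.641 with an estimated correlation). They included the VEGF receptor gene Kdr (1.39-fold), Egfl7 (1.36-fold) and the tight junction gene Cldn5 (1.23-fold). Of 15 ependymal and ciliary genes 3 fell (9 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 1.04e-07, and adjusted p = 0.641 with an estimated correlation). The dynein gene Dnah5 fell 2.27-fold, Tmem212 2.60-fold and Fam183b 2.43-fold, while Dnah9 was at 23.2 and 21.8 ± 1.49 CPM. DESeq2 did not call Abcc9, Kdr, Egfl7 or Cldn5 (adjusted p = 0.152, 0.0553, 0.118 and 0.293).

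Astrocyte genes fell in 7 of 18 cases and rose in 0 (10 and 0 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 2.00e-10, and adjusted p = 0.641 with an estimated correlation). Gfap, the astrocyte intermediate filament gene, fell 2.42-fold, the water channel gene Aqp4 from 197.2 to 132.7 ± 4.80 CPM and Clu 1.46-fold, while Apoe was at 722.4 and 580.7 ± 17.7 CPM (adjusted p = 0.0984). The Gfap call was lost in a robust fit (adjusted p = 0.130). In the reactive astrocyte list, Gfap and the small heat shock gene Hspb1 were the 2 of 13 members that fell, also adjusted over the list alone (camera adjusted p = 1.52e-04, and adjusted p = 0.641 with an estimated correlation). The list's median was -0.32, and -0.54 without FGR replicate 2, and Vim and Cd44 were not called (adjusted p = 0.322 and 0.136). Of 13 oligodendrocyte precursor genes 4 fell, or 8 adjusted over the list alone (camera adjusted p = 1.72e-08, and adjusted p = 0.641 with an estimated correlation). They included Gpr17 (1.47-fold), Olig1 (1.36-fold) and the PDGF receptor gene Pdgfra (1.29-fold), with Ptprz1 at 658.2 and 569.1 ± 28.0 CPM. In the list of myelin and oligodendrocyte genes, Cnp was the 1 of 17 that fell (1.21-fold), also adjusted over the list alone. The list's camera adjusted p was 0.0192, and the adjusted p = 0.641 with an estimated correlation. Its call was lost under a stricter filter (adjusted p = 0.0739), with protein-coding genes alone (adjusted p = 0.0634) and without X- and Y-linked genes (adjusted p = 0.0575). The Cnp call was lost in DESeq2 (adjusted p = 0.326), limma-voom (adjusted p = 0.0638) and a GC and length offset (adjusted p = 0.0799). Mbp, which encodes myelin basic protein, was at 53.2 and 53.1 ± 0.286 CPM, and Cldn11 and Bcas1 were not called (adjusted p = 0.0907 and 0.134).

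Microglial genes were lower in both FGR libraries for 16 of 18 members, of which 4 fell (8 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 1.06e-07, and adjusted p = 0.641 with an estimated correlation). The microglial gene Fcrls fell from 14.0 to 6.81 ± 0.0232 CPM, the integrin gene Itgam 2.04-fold and the CSF1 receptor gene Csf1r 1.37-fold. In the list of reactive microglia and macrophages 4 of 15 members fell, or 5 adjusted over the list alone (camera adjusted p = 2.66e-05, and adjusted p = 0.641 with an estimated correlation). The median was -0.71, with -0.83 in FGR replicate 1 and -0.40 in FGR replicate 2, and -0.42 when fitted without FGR replicate 1. Mrc1, the macrophage mannose receptor gene, fell from 27.4 to 11.3 ± 3.87 CPM, Spp1 2.06-fold and F13a1 1.97-fold, while Igf1 was at 34.6 and 30.7 ± 0.306 CPM. Of 23 interferon response genes 4 fell, or 5 adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.732 with an estimated correlation). The median was -0.18, and -0.35 without FGR replicate 2. Ifit2 fell 1.51-fold, Ifit3 2.39-fold and Ifi27 2.01-fold, and H2-D1 was at 31.9 and 32.1 ± 0.129 CPM. The calls of Mrc1 and F13a1 were lost in DESeq2 (adjusted p = 0.359 and 0.718) and in a robust fit (adjusted p = 0.465 and 0.582), and the interferon list's call under a stricter filter (adjusted p = 0.0501) and with protein-coding genes alone (adjusted p = 0.0576). DESeq2 did not call Csf1r (adjusted p = 0.0685), and Ifit3 was not called with protein-coding genes alone (adjusted p = 0.0535).

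**Figure D3:**
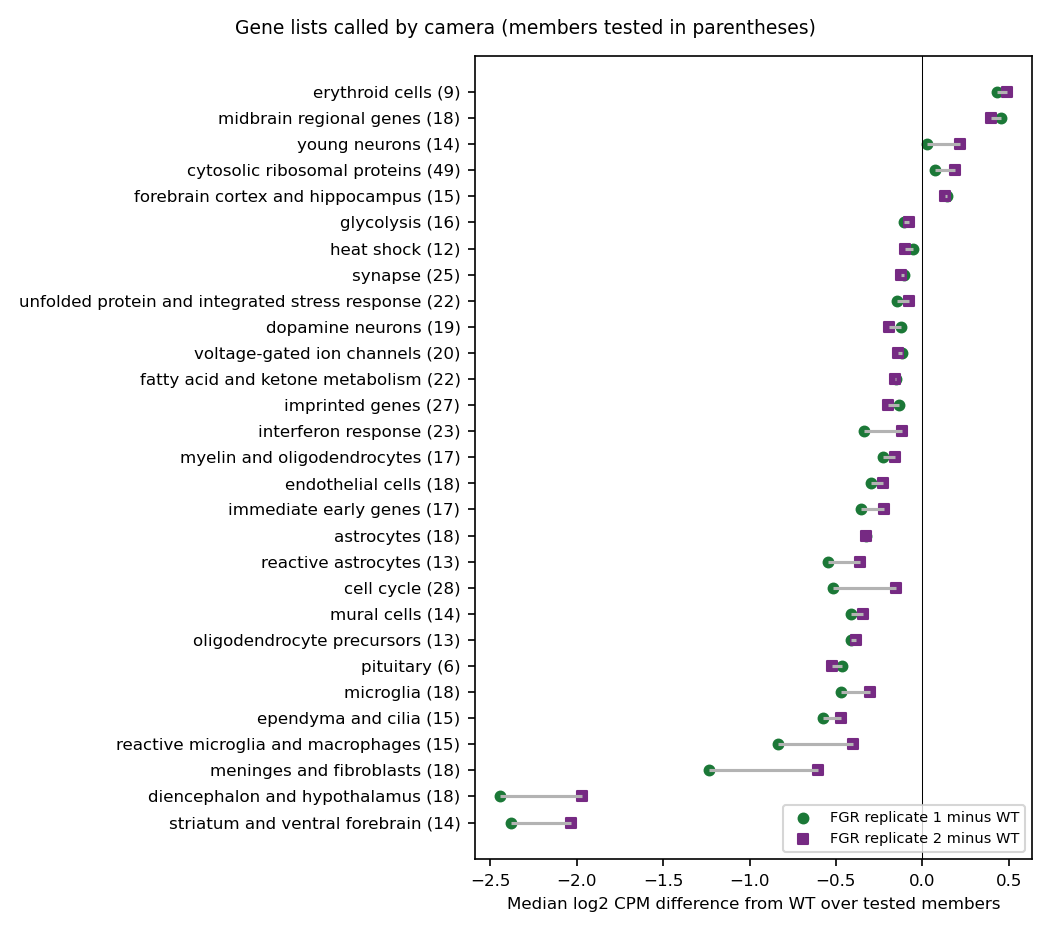
Median log2 CPM difference from WT (x axis) over the tested members of each of the 29 gene lists that camera called, for FGR replicate 1 (green circles) and FGR replicate 2 (purple squares), with the number of tested members in parentheses. The diencephalon and hypothalamus list lay at -2.44 and -1.97, and the midbrain list at 0.45 and 0.40.

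The list of young neuron genes was called higher (camera adjusted p = 0.00487, and adjusted p = 0.641 with an estimated correlation). Of 14 members 3 rose and 0 fell (6 and 0 adjusted over the list alone), 7 were higher in both FGR libraries and 4 lower in both. The median log2 fold change was 0.29, and 0.03 without FGR replicate 2. Sox11 was at 278.1 and 410.7 ± 32.2 CPM, Nhlh2 rose 1.36-fold and Sox4 1.27-fold, and Tubb3 was at 1311 and 1190 ± 3.61 CPM. The Sox4 call was lost when libraries were scaled by their totals (adjusted p = 0.0705) or by size factors (adjusted p = 0.0507). Of 25 synapse genes 5 fell, or 6 adjusted over the list alone, where 1 rose (camera adjusted p = 0.00232, and adjusted p = 0.732 with an estimated correlation). The scaffold genes Shank1 and Shank3 fell 1.46-fold and 1.33-fold and the vesicle gene Syn1 1.43-fold. Of 20 ion channel genes the calcium channel genes Cacna1a (1.34-fold) and Cacna1g (1.24-fold) fell, or 4 genes adjusted over the list alone, where 1 rose (camera adjusted p = 0.00947, and adjusted p = 0.641 with an estimated correlation). The sodium channel genes Scn1a and Scn3a were not called (adjusted p = 0.0593 and 0.236). The immediate early genes Fos, Fosb and Jun, which respond to neuronal activity and handling, fell 2.75-fold, 3.94-fold and 1.43-fold, the 3 of 17 members that were called (4 fell adjusted over the list alone). The list's camera adjusted p was 2.67e-04, and the adjusted p = 0.641 with an estimated correlation. Fosb was at 3.12 CPM in WT and at 1.12 and 0.416 CPM in the FGR libraries, 7.47-fold lower without FGR replicate 1. Among 28 cell cycle genes Ccnb1 fell 1.72-fold, and 3 fell adjusted over the list alone (camera adjusted p = 1.52e-04, and adjusted p = 0.732 with an estimated correlation). The cell cycle median was -0.51 in FGR replicate 1 and -0.15 in FGR replicate 2, Cdk1 and Aurkb were not called (adjusted p = 0.0620 and 0.0689), and Pcna was at 49.1 and 47.6 ± 3.28 CPM. A GC and length offset ended the calls of the ion channel list (adjusted p = 0.213) and Cacna1g (adjusted p = 0.0598), a robust fit that of Fosb (adjusted p = 0.0827), and DESeq2 those of Shank3, Cacna1g, Nhlh2 and Ccnb1 (adjusted p = 0.0622, 0.0892, 0.155 and 0.273).

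Of 16 glycolysis genes 4 fell, or 6 adjusted over the list alone (camera adjusted p = 3.84e-04, and adjusted p = 0.641 with an estimated correlation). Pfkl fell 1.41-fold, Tpi1 1.36-fold, Eno2 1.34-fold and Ldha 1.27-fold, while Pfkp was at 608.8 and 589.0 ± 18.8 CPM. The median was -0.07, and -0.11 without FGR replicate 2. Of 22 genes of fatty acid and ketone metabolism 3 fell, or 4 adjusted over the list alone (camera adjusted p = 4.22e-04, and adjusted p = 0.641 with an estimated correlation). Oxct1, which lets cells use ketone bodies, fell from 349.2 to 222.1 ± 6.89 CPM, the monocarboxylate transporter gene Slc16a1 1.22-fold and Scd1 1.35-fold, and Scd2 was at 1022 and 854.0 ± 38.8 CPM. The chaperone genes Hspa1a (1.46-fold), Hspa1b (1.49-fold), Hsph1 (1.33-fold) and Hspb1 (1.90-fold) fell among 12 heat shock genes, also adjusted over the list alone (camera adjusted p = 0.00947, and adjusted p = 0.641 with an estimated correlation), with Hspa8 at 2060.5 and 1960 ± 23.4 CPM. Hspa5 (1.33-fold), Pdia4 (1.31-fold), Xbp1 (1.27-fold) and Slc7a11 (1.29-fold) fell among 22 genes of the unfolded protein and integrated stress response (5 fell and 1 rose adjusted over the list alone). That list's camera adjusted p was 0.0275, and the adjusted p = 0.641 with an estimated correlation, its median was -0.12, and -0.08 without FGR replicate 1, and a GC and length offset ended its call (adjusted p = 0.0568). DESeq2 did not call Scd1, Hsph1, Slc7a11, Xbp1 or Slc16a1 (adjusted p = 0.0521, 0.0820, 0.0844, 0.0884 and 0.224), nor limma-voom Hspb1 (adjusted p = 0.0568).

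Haemoglobin genes rose. Hba-a1 was at 51.4 CPM in WT and 89.3 ± 11.1 CPM in FGR, and Hba-a2 and Hbb-bs rose 1.71-fold and 1.38-fold, and Hbb-bt from 38.7 to 58.1 ± 2.40 CPM. Of 9 erythroid genes 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 3.91e-09; adjusted p = 0.641 with an estimated correlation), and without the haemoglobin genes the list was not called (adjusted p = 0.183). Cytosolic ribosomal protein genes were called higher as a list (camera adjusted p = 2.47e-05, and adjusted p = 0.732 with an estimated correlation). The median was 0.13 and 41 of 49 members were higher in both FGR libraries, although Rpl38, the 1 member called, fell 1.20-fold (0 called adjusted over the list alone), a call lost in DESeq2 (adjusted p = 0.248). The list's median was 0.07 in FGR replicate 1 and 0.19 in FGR replicate 2, and 0.07 when fitted without FGR replicate 2. Rpl22 and Rpl27 were at 134.2 and 161.9 ± 7.48 CPM and at 123.8 and 148.2 ± 15.7 CPM (adjusted p = 0.0586 and 0.116). Of 27 imprinted genes 5 fell and 0 rose, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.85e-06; adjusted p = 0.641 with an estimated correlation), among them H19 1.91-fold, Zim1 1.49-fold, Dlk1 2.35-fold and Igf2 1.90-fold, with Meg3 at 2935 and 2663 ± 61.7 CPM. Igf2 is also a member of the meninges list, and the log2 differences from WT in FGR replicates 1 and 2 were -1.26 and -0.65 for Igf2 and -1.18 and -0.71 for H19, beside meningeal medians of -1.24 and -0.61. H19 and Igf2 were not called in DESeq2 (adjusted p = 0.279 and 0.525) or in a robust fit (adjusted p = 0.518 and 0.610).

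Camera called 29 of 54 lists, 5 higher and 24 lower in FGR, and left 25 uncalled. With an estimated correlation, a test on 1 degree of freedom that hardly any list could pass, 0 lists passed. Fry called 1, apoptosis and autophagy (adjusted p = 0.00745), which camera did not call (adjusted p = 0.112). The lists for hypoxia, glucocorticoid response, the IGF and insulin axis and the choroid plexus were not called (adjusted p = 0.130, 0.220, 0.467 and 0.473). Camera on DESeq2's statistics, at the same preset correlation, called 9 of the 25 uncalled lists, among them hypoxia (adjusted p = 0.0182). Vegfa fell 1.49-fold among hypoxia genes and Aldoa was not called (adjusted p = 0.0800). Among glucocorticoid response genes Pdk4 fell 2.16-fold, while Per1, Hsd11b1 and Tsc22d3 were not called (adjusted p = 0.0859, 0.139 and 0.552). Igfbpl1 rose from 6.43 to 17.2 ± 2.72 CPM, and the binding protein genes Igfbp2 and Igfbp5 fell 1.56-fold and 1.27-fold. Calml4 fell 1.96-fold among choroid plexus genes, and Ttr, Kl and Enpp2 were not called (adjusted p = 0.0561, 0.304 and 0.418). The median, mean and test differed in sign for the cortex, neural progenitor, muscle and bone, IGF axis, mitochondrially encoded, nuclear oxidative phosphorylation and nuclear noncoding RNA lists. Further calls of named genes ended under other settings. With protein-coding genes alone, Sox4, Ccnb1, Cldn5, Calml4, Pdk4, F13a1, Rpl38, Hspb1 and Tbx19 were not called (adjusted p from 0.0505 to 0.0832). Under a stricter filter, Rpl38, Ptgds, F13a1, Ccnb1 and Sox4 were not called (adjusted p from 0.0526 to 0.102). In limma-voom, Slc16a1, Cldn5 and Rpl38 were not called (adjusted p = 0.0505, 0.0611 and 0.0698), and without abundant RNA genes Sox4 was not (adjusted p = 0.0520). With a GC and length offset, Rpl38 and Cldn5 were not called (adjusted p = 0.0740 and 0.1249).

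A count by size, with no test, gave 99 of 18667 genes that differed at least 2-fold from WT in the same direction in both FGR libraries, 35 higher and 64 lower. In all, 322 genes differed 2-fold between WT and FGR replicate 1, 186 between WT and FGR replicate 2, and 87 between the FGR libraries. With FGR replicate 1 in the place of WT the count was 37, and with FGR replicate 2 it was 27. Simulated libraries with no effect gave a mean of 6.32 and at most 11 such genes in 100 draws, with WT set to vary like the FGR libraries. Independent lists would share 0.218 genes higher and 1.65 lower. Part of the excess may come from the shared WT library, which cannot be split.

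The FGR libraries also differed from each other. Of the 87 genes, 71 were higher in FGR replicate 2 and 16 lower. Xist, transcribed from the inactive X chromosome of females, was at 541.2 CPM in WT, 591.1 CPM in FGR replicate 1 and 1.71 CPM in FGR replicate 2. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 counts in WT, 1 to 3 counts in FGR replicate 1, and 64.4, 59.7, 43.8 and 37.8 CPM in FGR replicate 2.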

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

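The GC and length offset, protein-coding genes alone and removal of X- and Y-linked genes were chosen after the data had been seen. The total of 1087 called genes stayed within 1.5 times under 9 of 12 alternatives. It was 2057 (695 higher, 1362 lower) with no filter on low counts, 357 (128 and 229) in DESeq2 and 1952 (814 and 1138) at an adjusted p under 0.1. The unfiltered edgeR fit tested 35837 genes and also called Xist (adjusted p = 3.98e-22), at 541.2 CPM in WT and 591.1 and 1.71 CPM in the FGR libraries. Its calls therefore did not require the FGR libraries to be alike, and they are not comparable with 1087. Scaling by totals alone gave 1027 lower genes, the stricter filter 253 higher genes and the GC and length offset 726 higher genes; the cause was not tested. No scaling moved the median of all genes by over 0.1 on the log2 scale. Of the 29 list calls, 0 held with an estimated correlation and 0 in fry, which called 1 other list, apoptosis and autophagy. The estimated correlation rested on 1 degree of freedom, so the loss of calls under it was close to fixed in advance. Lists called only under an alternative, with no turn of direction, numbered 9 in DESeq2 (neuropeptides, neurotrophins, neural progenitors, cerebellum, hypoxia, oxidative stress, cholesterol synthesis, sex-linked transcripts, and apoptosis and autophagy, adjusted p from 6.51e-05 to 0.0385), 3 each in limma-voom, under scaling by totals and with the GC and length offset, 2 with no filter and 4 at an adjusted p under 0.1.

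Genes 2-fold from WT on the same side numbered 26 at a mean CPM of at least 5, 165 at 0.5 and 579 at 1.5-fold. Those between the FGR libraries numbered 26, 196 and 558. Against a single FGR library the first count was 186 to 322, since only 1 library had to pass. With 1 library on each side, counts of called genes and lists cannot be given, and those fits give values with no test. Without FGR replicate 1 and without FGR replicate 2, values moved by over the spread between the FGR libraries for 7 and 5 of the called named genes and for 7 and 12 of the called lists. That spread was the SD of the 2 FGR libraries, and removal of 1 of 2 shifts their mean by less. Most values therefore had to stay within it, and these counts do not measure stability. The robust fit does not enter camera.

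Of the 106 named genes that were called, 24 lost the call in DESeq2, 11 in the robust fit, 11 with protein-coding genes alone, 7 in limma-voom, 6 under the stricter filter and 4 with the GC and length offset. Others had no adjusted p: 31 under the stricter filter, which left 75 to compare, 26 in DESeq2, which left 80, 4 without abundant RNA genes, 3 with protein-coding genes alone and 1 without X- and Y-linked genes. Of the 41 named genes that were not called, 17 were called with no filter, 14 at an adjusted p under 0.1, 12 with the GC and length offset, 8 under scaling by totals, 6 by size factors, 6 without X- and Y-linked genes, 4 in limma-voom, 3 in DESeq2 and 1 with protein-coding genes alone. None of the named calls changed sign under the alternatives run. For removal of 1 FGR library this follows from both libraries lying on the same side of WT. Uncalled values near 0 turned. Under scaling by totals Rpsa was at -0.00097 and H2-D1 at -0.0318. H2-D1 was also at -0.0075 with no filter, -0.0080 under the stricter filter and -0.0016 without abundant RNA genes. With the GC and length offset Dnah9 was at 0.0331 and Mbp at 0.0484, and Mbp was at 0.0109 with protein-coding genes alone. List tests that turned had medians of -0.15 (totals), 0.0431 (no filter), -0.0566 (offset) and -0.0510 (protein-coding) for muscle and bone. The medians were -0.0586 (totals), -0.0346 (stricter filter) and -0.13 (offset, where the list was called lower, adjusted p = 7.87e-04) for mitochondrially encoded transcripts, 0.0921 (stricter filter) for the thyroid hormone axis, 0.0041 (totals), 0.0320 (stricter filter) and 0.0437 (fry) for nuclear noncoding RNAs, and 6.71 (limma-voom) for sex-linked transcripts. The cause was not tested.

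No paired analysis was possible because the groups share only replicate number 1. With 1 WT and 2 FGR libraries of this depth, edgeR called 47.8% of simulated 1.5-fold changes in genes at a mean CPM of at least 1. Changes of that size may be missed.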

Other observations

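The tests of library scaling, of meningeal against endothelial genes and of genes shared with noradrenergic neurons were chosen after the results had been seen. The genes named in the next paragraph were chosen after their values were seen.

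Several gene groups differed between the FGR libraries. Of 16 cerebellar genes 15 were higher in FGR replicate 2 than in FGR replicate 1, with a median log2 difference of 0.63, as were 27 of 28 cell cycle genes (median 0.43), 18 of 18 meningeal genes (median 0.65), 48 of 49 cytosolic ribosomal protein genes (median 0.12), 16 of 18 microglial genes (median 0.14) and 15 of 15 mitochondrially encoded genes, against 50.8% of all tested genes. Fewer members were higher in FGR replicate 2 for synapse (3 of 25, median -0.04), axon guidance (3 of 22, median -0.09), glutamate neuron (2 of 13, median -0.08), GABA neuron (3 of 13, median -0.12) and serotonin neuron genes (2 of 9, median -0.10). Fat2, a cadherin gene of cerebellar granule cells, was at 6.07 CPM in WT, 3.67 in FGR replicate 1 and 20.2 in FGR replicate 2. Eomes was at 0.427, 0.776 and 3.08 CPM, and Calb1, a calcium-binding protein gene of Purkinje cells, at 31.6, 17.0 and 40.3 CPM. Mki67, a marker of dividing cells, was at 23.7, 11.6 and 23.4 CPM. These are values of single libraries with no test.

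As groups, hypothalamic genes were lower and hindbrain Hox genes higher in both FGR libraries. Cerebellar genes were not higher in both, with medians against WT of -0.28 in FGR replicate 1 and 0.53 in FGR replicate 2. The hypothalamic median nearest 0 over 3 scalings was -2.38 while the midbrain median stayed at 0.35 or above. These scalings moved the median of all genes only between 0.005 and -0.034, so they could not have brought either list to 0. A scaling error would shift all genes alike and leave the gap between the 2 lists unchanged, which argues against scaling as the cause of that gap. A second list of 14 hypothalamic genes, fixed before its values were seen, had a median of -0.79 over 13 tested genes, and 0 of 10000 random lists matched on expression lay as low. Its most abundant gene, Irs4, was at 41.9 CPM in WT and 25.2 and 23.1 CPM in FGR, and 6 of its genes stayed at 1 CPM or more in FGR. Random lists hold unrelated genes, whereas genes of 1 region or cell type can move together with the single WT library. The second lists rest on the same 3 libraries, so such ranks cannot tell a group effect from a difference of that WT library. A second list of pons and medulla genes (most abundant Evx2, at 5.65 CPM in WT and 7.02 and 7.50 CPM in FGR) had a median of 0.51 over 10 tested genes. Of these 8 were higher and 2 lower, and 1 was called. Of 10000 random lists, 9999 lay at or below that median. FGR pieces that held less hypothalamus and more pons and medulla are a candidate explanation, and an effect of the FGR state stays open, as untested.

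Meningeal genes were lower in both FGR libraries. A lower share of all non-neuronal cells alone would lower meningeal and endothelial genes alike, but meningeal members lay 0.68 lower on the log2 scale (difference -0.68). The two-sided permutation over genes gave p = 0.00001, the smallest that 100000 resamples can give, and took the members as independent. The endothelial mean of -0.19 was nearer 0 than those of the astrocyte (-0.39), microglial (-0.44) and mural (-0.41) lists. A lower non-neuronal share beside a further meningeal fall therefore stays open, as untested. A second list of 14 meningeal genes had a median of -0.72, and 0 of 10000 matched random lists, again of unrelated genes, lay as low. Its most abundant gene, Col12a1, was at 36.9 CPM in WT and 16.7 and 23.0 CPM in FGR. FGR pieces with less meninges may account for this, and a change in the meninges themselves in FGR mice stays open, as untested.

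Dopamine neuron genes moved apart from each other. A second list of 9 dopamine neuron genes had a median of -0.56, with 8 of 9 lower, of which 2 were called. Of 10000 matched random lists of unrelated genes, 1 lay as low. FGR pieces with fewer dopamine neurons may show such a fall. The second list's most abundant gene, Klhl1, was at 43.7 CPM in WT and 41.8 and 41.3 CPM in FGR. In the first list 5 of 19 members fell, and En1 and Otx2, also in the midbrain list, rose. The other 12 were not called, among them Foxa2 and Lmx1b (edgeR adjusted p = 0.716 and 0.752). The 6 members of the first dopamine list that noradrenergic neurons also use had a mean log2 fold change of -0.11 against -0.33 for the other 13 (two-sided exact permutation p = 0.392). Against 7 of those 13, with a mean of -0.72, the exact permutation p = 0.0134. These 7 were picked with the values in view, so that p carries no weight. The comparison with all 13 did not decide, and reads from noradrenergic neurons in the shared genes stay open. A loss of dopamine transcripts within neurons of FGR mice was not tested and stays open.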
